A study of Mus musculus with 24 samples.

How the data were processed

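Gene expression was measured by RNA sequencing of the hippocampus of male mice aged 2 to 4 months, with the RNA of 3 mice pooled in each library. The 24 sample records describe 18 libraries, since each of the 6 libraries of the inducible line has a record for either read of a pair and 1 count file. Per the labels' protocols the libraries were stranded, with single reads of 50 nt for the KO and wild-type libraries and paired reads of 75 nt for the inducible line, on 2 flowcells. Tissue is hippocampus per the labels, although the extraction text speaks of cultures, and whether control mice carried Cre or received tamoxifen is not given in the sources used here.

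The deposited files hold raw counts per Ensembl gene, without normalization. Per the submitters' processing notes STAR 2.5.0c, SAMtools 1.3, HTSeq 0.6.1 and DESeq2 were used with build GRCm38. The strand setting of HTSeq and the annotation release are not given in the sources used here. Each file lists 47069 gene IDs, of which 46574 were given a symbol, position and biotype from GENCODE M21 and 495 were not. The summary lines at the end of each file were left out of the counts. Reads in no feature made up 14.7 to 17.2% of gene, no-feature and ambiguous reads together, and ambiguous reads 0.765 to 1.06%. Counts in genes ranged from 16 to 45.6 M per library.

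Counts were analysed in R 4.3.3 with edgeR 4.0.16. Libraries were scaled by TMM, genes were kept by filterByExpr (minimum count 10, minimum total 15), and each comparison was an edgeR quasi-likelihood test with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. Fitted log2 fold changes use a prior count of 0.125. The 4 groups of KO and wild type were fitted together (12 libraries), the inducible line alone (6 libraries), and the difference between both mutants in a fit of all 18 libraries. CPM use TMM factors, except the sum of the 7 germline genes, which is per M counts in genes. The groups, the comparisons, the tests, the gene lists, the rule for named genes and all alternatives but those named as later ones below were set before the data were examined.

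The 21 gene lists were germline genes, immediate early genes, delayed activity-regulated genes, glucocorticoid response, regulators of H3K4 methylation, synaptic and glutamatergic genes, clustered protocadherins, mitochondrially encoded genes, hypoxia and heat shock genes, interferon and antigen presentation genes, and markers of dentate gyrus, CA1, CA2 and CA3, inhibitory neurons, astrocytes, oligodendrocyte lineage, microglia, endothelial and mural cells, choroid plexus, thalamus with striatum and habenula, and blood. The germline list was written from knowledge of genes of that class. Lists were tested with camera of limma 3.58.1 on voom values, with a preset correlation of 0.01 and adjustment over the lists of a comparison. Of 147 tests 60 passed. With an estimated correlation 4 did: germline genes in untreated KO, in KO after novelty and in the difference between KO and ifKO, and glucocorticoid response genes after novelty in KO. The fry test, which asks whether the genes of a list move on balance one way, called 14. Its mixed form asks for change in either direction, and neither form compares a list with other genes.

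Kdm5c was named first. The genes with the largest changes had an adjusted p under 0.05, a mean of at least 1 CPM in either group and no overlap between the groups' libraries, which chance gives for 10% of genes at 3 against 3. Of these the 10 largest rises and the 10 largest falls were named. For contrasts of differences it was 5 and 5, without the rule on overlap. Then up to 4 members per list and direction with an adjusted p under 0.05 were named, whatever their level, so D1Pas1 and Cyct can lie under 1 CPM. A gene without a count in a group was compared with a floor of 3 counts over the group. Ratios from 1 to 3 counts carry a 95% counting interval.

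Alternatives were DESeq2 1.42.0, RLE factors, no low-count filter, a stricter filter (1 CPM in 3 libraries), the replicate number as a block, only the groups compared, a test against a fold change of 1.2, and each library left out in turn. Further alternatives were chosen after seeing the data: leaving out both deviating novelty libraries, also with offsets, offsets for GC content and length of the longest transcript, and leaving out Esr1 and genes near Camk2a. The methods were tested on simulated counts with the same groups and library sizes. Changed genes had a mean of at least 1 CPM. Counts were drawn independently, with the spread fitted for genes of like level and without the trend with GC content and length described below. The shares that follow therefore do not cover genes of lower level or that trend. In the comparison of untreated KO with wild type 74.6% of 1.5-fold, 96.0% of 2-fold and 100% of 4-fold changes were recovered, with 5.6% false calls. For ifKO the shares were 84.1%, 98.5% and 100% with 6.3% false, and for the difference between both mutants 51.2%, 86.6% and 100% with 4.6% false. For the interaction they were 35.8%, 81.6% and 98.5% with 5.5% false. Raw reads were not analysed here.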

Results

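Messenger RNA of the hippocampus of adult male mice was sequenced in 18 libraries, each made from the pooled RNA of 3 mice, in 6 groups of 3 libraries. Kdm5c, an X-linked gene, encodes a demethylase of lysine 4 of histone H3. Mice lacking Kdm5c in every cell (KO) and wild-type littermates were taken either untreated or after 1 h of exploring a box with tubing and toys (novelty), on a mixed C57 and 129 background. The other pair of groups compared an inducible forebrain knockout (ifKO), in which a tamoxifen-dependent Cre recombinase under the Camk2a promoter deletes Kdm5c in excitatory neurons of the adult forebrain, with control mice on a C57BL/6J background. The counts assigned to genes, in M, were 16, 21.9 and 23.4 in the untreated wild-type libraries 1, 2 and 3, and 45.6, 22 and 29.5 in the untreated KO libraries. After novelty they were 27.6, 31.4 and 21.3 in wild type and 22.1, 16.7 and 20 in KO. The control libraries of the inducible line held 38.5, 37.4 and 44, and the ifKO libraries 43.1, 38.6 and 36.3. Each library is a pool, so the SE, the SD and the p-values of single genes measure the spread between pools and not between mice. Camera compares the genes of a list with other genes. Fisher and permutation p-values and the interval of a median ratio are computed over genes, and counting intervals over counts. Fold changes are log2 values with the standard error (SE) of the fit and n = 3 libraries per group.

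Kdm5c itself (chromosome X, 152233020 to 152274535, GRCm38) was read in every library. In untreated wild type it stood at 75.4, 74.2 and 76.4 CPM (counts per M counts in genes, with normalization factors) and in untreated KO at 75.8, 76.3 and 75.4 CPM. After novelty the values were 100, 90.2 and 96.0 CPM in wild type and 78.5, 77.8 and 86.5 CPM in KO. The controls of the inducible line had 62.1, 67.5 and 62.4 CPM and the ifKO libraries 69.0, 63.6 and 65.3 CPM. The log2 fold change was 0.01 ± 0.06 in untreated KO (adjusted p = 0.983) and 0.04 ± 0.05 in ifKO (adjusted p = 0.927). In KO after novelty it was -0.24 ± 0.06 (adjusted p = 0.1075), with every KO library below every wild-type library. A count over the whole gene cannot show a deletion of some of its exons, so these levels check neither the genotype nor the deletion.

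The comparison of untreated KO with untreated wild type asked which genes differ at rest when Kdm5c has been missing throughout life. Genes of the germline, which adult brain keeps at low levels, were among the largest rises. Tex14, needed for the bridges between germ cells (chromosome 11, 87405065 to 87555823), rose by 3.85 ± 0.16, from a mean of 0.803 to 12 CPM (adjusted p = 1.53e-08). Cacng6, a calcium channel gamma subunit (chromosome 7, 3424195 to 3435667), rose by 3.27 ± 0.10, from 3.07 to 29.5 CPM (adjusted p = 3.49e-10). Klk10, a kallikrein-related peptidase (chromosome 7, 43781035 to 43785410), rose by 3.43 ± 0.15. Among the genes that fell were Ogn, a small proteoglycan (chromosome 13, 49608046 to 49624501), by -1.57 ± 0.35, and Mcm6, a subunit of the replicative helicase (chromosome 1, 128331590 to 128359664), by -0.75 ± 0.13.

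In all, 178 genes rose and 26 fell in untreated KO, of 16392 tested. Of these, 94 of the higher and 9 of the lower genes differed by over 2-fold. The other named genes that rose most were the noncoding RNAs Gm28286 (3.59 ± 0.34) and A830008E24Rik (3.33 ± 0.35), which lie side by side on chromosome 1, the pseudogene Fbxw23 (3.17 ± 0.31) and 4930524B15Rik (3.12 ± 0.28). Of the genes that fell most, Cd36 encodes a fatty acid receptor (-1.43 ± 0.28), Ano2 a chloride channel (-0.94 ± 0.20) and Alox8 a lipoxygenase (-0.75 ± 0.14). Hoga1 (-1.06 ± 0.22), Ccn4 (-1.05 ± 0.22), Pirt (-1.03 ± 0.18), Htra4 (-0.99 ± 0.20) and Fhod3 (-0.78 ± 0.17) also fell.

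Of 42 germline genes 19 had enough counts to be tested, in some cases, such as D1Pas1 and Naa11, through their level in KO alone. Of these 19, 7 rose in untreated KO and none fell, and 9 rose when adjusted over the list alone. Naa11, a testis-expressed acetyltransferase subunit, had 3 counts over the untreated wild-type libraries and 220 over the KO libraries, a ratio of 46.3 per M counts (95% counting interval 15.6 to 226). D1Pas1, a testis RNA helicase, had no count in untreated wild type and 88 in KO, and was at least 18.5-fold higher, taking a floor of 3 counts over the group. Stk31, a germ cell kinase (3.32 ± 0.47), Cyct, the testis cytochrome c (3.27 ± 0.52), Sycp3 of the synaptonemal complex (1.29 ± 0.24) and Ddx4, a germ cell RNA helicase (0.97 ± 0.20), also rose. The list's median was 0.61, also with D1Pas1 at its bound (camera adjusted p = 3.84e-09; adjusted p = 0.00705 with an estimated correlation). Summed over the 7 genes, the level was 7.16 ± 0.364 counts per M (SD, n = 3) in untreated wild type and 29.4 ± 2.96 in untreated KO. Such intervals and floors cover counting error only.

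**Figure D1:**
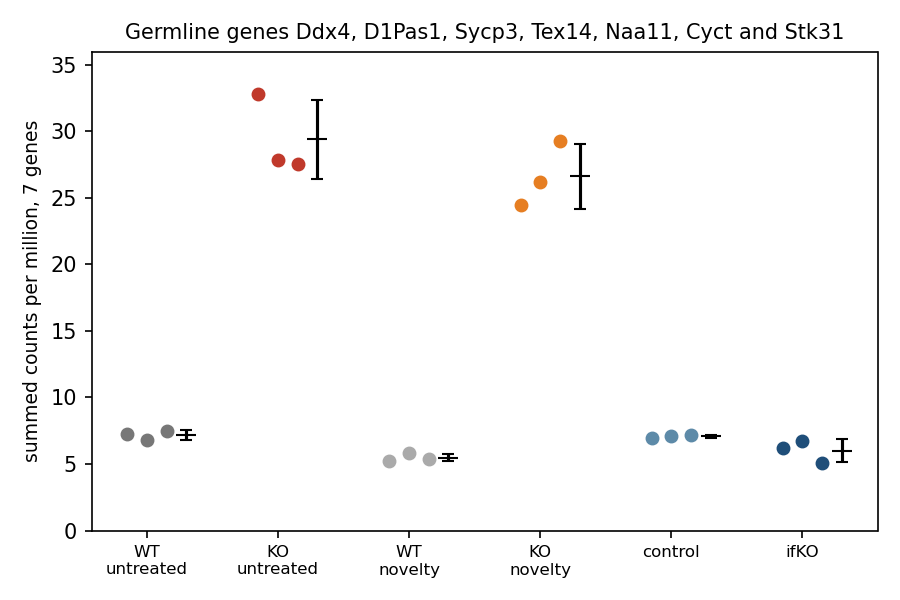
Summed counts per M of the 7 germline genes that rose in KO, for each library (points) in the 6 groups, with the mean and SD of 3 libraries (bars). The KO libraries lie between 24.5 and 32.8 and the wild-type, control and ifKO libraries between 5.07 and 7.48. The genes were taken because they rose in untreated KO, so the height of that group is not independent of the choice.

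Single members rose in 3 further lists. Of 15 microglia markers, Siglech (0.60 ± 0.10) and Fcrls (0.43 ± 0.08) rose, 2 also when adjusted over the list alone, and the list as a whole was not called (median 0.10, camera adjusted p = 0.148). Of 15 markers of the CA2 and CA3 fields Map3k15 rose (1.15 ± 0.17), 1 also when adjusted over the list alone, and 1 further marker was then lower (camera adjusted p = 0.0916). Map3k15 lies on chromosome X (159988433 to 160123351), within 10 Mb of Kdm5c. Of 18 glucocorticoid response genes Sgk1 rose (0.37 ± 0.08), 1 also when adjusted over the list alone (median 0.13, mean 0.00, camera adjusted p = 0.0413; adjusted p = 0.512 with an estimated correlation). None of the 34 immediate early genes passed over all genes and 2 were higher when adjusted over the list alone. Their median was 0.36, with 30 of 34 positive (camera adjusted p = 1.16e-08; adjusted p = 0.493 with an estimated correlation). The level of that list was 3.50, 4.30 and 4.01 mean log2 CPM in untreated wild-type libraries 1, 2 and 3 and lay between 3.96 and 4.54 over the untreated KO libraries.

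Choroid plexus markers had a median of 0.86 in untreated KO, with 16 of 16 positive, none past the threshold over all genes and 3 when adjusted over the list alone (camera adjusted p = 0.000646; adjusted p = 0.543 with an estimated correlation). That median went with untreated KO library 2, whose list level was 3.33 mean log2 CPM, while the other untreated KO and wild-type libraries lay between 0.67 and 1.27. No member passed over all genes in the following lists. The synaptic and glutamatergic genes had a median of 0.09 (camera adjusted p = 0.0131; adjusted p = 0.140 with an estimated correlation), and the astrocyte markers 0.13 (camera adjusted p = 0.00236; adjusted p = 0.301 with an estimated correlation). The oligodendrocyte lineage markers had -0.15 (camera adjusted p = 0.000336; adjusted p = 0.332 with an estimated correlation), with 2 lower when adjusted over the list alone. The endothelial and mural markers had -0.12 (camera adjusted p = 0.0229; adjusted p = 0.512 with an estimated correlation), with KO library 2 at 4.48 mean log2 CPM and the others at 4.76 to 5.02. Blood cell genes had -0.32 (camera adjusted p = 0.000646; adjusted p = 0.193 with an estimated correlation), with 1 of 7 lower when adjusted over the list alone. Interferon and antigen presentation genes had -0.11 (camera adjusted p = 0.0225; adjusted p = 0.512 with an estimated correlation).

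The lists not called in untreated KO were the delayed activity-regulated genes (median 0.10, camera adjusted p = 0.0509), regulators of H3K4 methylation (0.02, adjusted p = 0.636), CA1 markers (0.04, adjusted p = 0.459), clustered protocadherins (0.03, adjusted p = 0.406) and mitochondrially encoded genes (0.08, adjusted p = 0.459). Inhibitory neuron markers (median -0.01, adjusted p = 0.101) and markers of thalamus, striatum and habenula (-0.18, adjusted p = 0.0582) were not called either. When adjusted over the list alone 3 inhibitory neuron markers were lower, namely Calb2 (-0.59 ± 0.14), Pvalb (-0.29 ± 0.08) and Gad1 (-0.28 ± 0.09), and so were Calb2 in the thalamic list and Tdo2 of the dentate list, while 1 protocadherin was higher. Dentate gyrus markers had a median of 0.03 and a mean of -0.01 (adjusted p = 0.684), and hypoxia and heat shock genes a median of -0.06 and a mean of 0.02 (adjusted p = 0.479). Median and mean differed in sign in the dentate and the hypoxia lists.

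Noncoding genes, here all that are not annotated as protein coding, pseudogenes included, made up 42 of the 178 higher genes, or 23.6%, against 11.3% of genes not called (Fisher's exact test, two-sided, p = 4.27e-06). The test takes genes as independent, although some of these genes lie side by side. Of 76 tested genes within 10 Mb of Kdm5c, 1 was called (Fisher's exact test, two-sided, p = 0.616). Of 560 X-linked genes 8 were called, or 1.43% against 1.24% elsewhere (Fisher's exact test, two-sided, p = 0.696). Without KO untreated library 1 the count of changed genes was 121, without wild-type untreated library 2 it was 132 and without wild-type untreated library 1 it was 135. It was 122 against a fold change of 1.2, 318 (260 higher, 58 lower) with only the groups compared, 347 (266 and 81) without a low-count filter, 340 (271 and 69) with offsets for GC content and length, and 415 (323 and 92) without both novelty libraries named below. Of the 15 named higher genes 12, all but Siglech, Fcrls and Sgk1, stayed past the threshold without any single library, and of the 10 named lower genes none did. The call of Siglech ended without any 1 of 3 libraries, and those of Fcrls and Sgk1 without any 1 of 5. Leaving out KO libraries 1, 2 and 3 ended 13, 6 and 9 of these 25 calls, and wild-type libraries 1, 2 and 3 ended 9, 9 and 7.

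The same genotypes after novelty asked which genes differ when the animals have just explored. Germline genes were again among those that rose: Tex14 rose by 3.92 ± 0.16 (adjusted p = 1.57e-08), Cyct by 4.13 ± 0.57, and Sycp3 by 1.84 ± 0.26. A830008E24Rik (chromosome 1, 154037597 to 154117951) rose by 4.63 ± 0.39, Hsf2bp, which acts in meiosis (chromosome 17, 31944769 to 32036349), by 3.40 ± 0.37, and Cacng6 by 3.12 ± 0.10 (adjusted p = 6.16e-10). F9, a coagulation factor (chromosome X, 59999464 to 60030759), rose by 3.04 ± 0.31. Pdyn, the precursor of dynorphins, fell by 0.56 on the log2 scale (SE 0.11, chromosome 2, 129686565 to 129699844), and Mcm6 fell again, by -0.68 ± 0.13.

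In all, 196 genes rose and 23 fell of 16392 tested, and 97 of the higher and none of the lower genes differed by over 2-fold. Gm43089 (3.46 ± 0.44), Gm28286 (3.00 ± 0.30), Klk10 (2.96 ± 0.14) and Fbxw23 (2.91 ± 0.28) completed the 10 largest rises. Naa11 had 3 counts in wild type and 97 in KO, a ratio of 44.2 per M counts (95% counting interval 14.7 to 218), and D1Pas1 was at least 15-fold higher, with no count against 33. The genes that fell included Fam198b (-0.96 ± 0.18), the helicase Recql4 (-0.89 ± 0.19), the homeobox gene Zfhx2 (-0.56 ± 0.07), the kinesin Kif26b (-0.54 ± 0.08) and Npnt (-0.53 ± 0.09). Mir6236, Gm15624 and Plk5 fell by -0.65 ± 0.13, -0.55 ± 0.11 and -0.55 ± 0.12.

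After novelty 7 of 19 germline genes rose in KO, and 13 when adjusted over the list alone, with a median of 1.09, also with D1Pas1 at its bound (camera adjusted p = 2.03e-17; adjusted p = 0.000745 with an estimated correlation). Siglech rose among the microglia markers (0.51 ± 0.10) and Map3k15 among the CA2 and CA3 markers (0.80 ± 0.17). Neither list was called: microglia markers had a median of -0.03 and a mean of 0.01, with 6 of 15 positive and 2 higher when adjusted over the list alone (camera adjusted p = 0.942), and CA2 and CA3 markers 0.04, with 2 higher and 1 lower when adjusted over the list alone (camera adjusted p = 0.549). None of the glucocorticoid response genes passed over all genes, and 5 were higher and 1 lower when adjusted over the list alone (median 0.17, camera adjusted p = 0.000225; adjusted p = 0.293 with an estimated correlation). Mitochondrially encoded genes had a median of -0.21, negative in 9 of 9 (camera adjusted p = 4.81e-05; adjusted p = 0.293 with an estimated correlation). Dentate gyrus markers had a median of -0.14 (camera adjusted p = 0.00693; adjusted p = 0.599 with an estimated correlation), where wild-type novelty library 2 was at 6.19 mean log2 CPM and the other novelty libraries at 5.63 to 5.92, and astrocyte markers 0.14 (camera adjusted p = 0.00306; adjusted p = 0.293 with an estimated correlation). Noncoding genes made up 20.4% of the higher genes (Fisher's exact test, two-sided, p = 0.000258), and 2 of 76 genes near Kdm5c were called (Fisher's exact test, two-sided, p = 0.271). Map3k15 was 1 of these 2.

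The genotype effect met itself across both treatments: 140 genes rose and 4 fell in KO in both, where 2.13 and 0.036 are given by n1 × n2 / N for independent lists, and no gene changed in opposite directions. Of the 204 genes called in untreated KO, 202 had the same sign after novelty (Pearson r = 0.928 across genes, which are not independent replicates). The treatments share no library, but both contrasts come from the same fit, with the same filter and 1 spread per gene. The lists are therefore not independent, and n1 × n2 / N is only a rough guide. Wild-type novelty library 1 and KO novelty library 2 stood apart from their groups, and without both of them 705 genes were called after novelty, 406 higher and 299 lower against 196 and 23. This leaves wild-type libraries 2 and 3 against KO libraries 1 and 3, which lie on opposite sides of a trend with GC content and transcript length, so the 705 mix genotype with that trend. Without KO novelty library 1 the count was 144, and without wild-type novelty library 3 it was 145. With only the groups compared it was 104 (102 higher, 2 lower), against a fold change of 1.2 it was 126 (124 and 2), and with offsets for GC content and length 354 (291 and 63). Of the 14 named higher genes 12, and of the 10 named lower genes Zfhx2 and Kif26b, stayed past the threshold without any single library. KO novelty libraries 1, 2 and 3 ended 9, 4 and 6 of the 24 calls when left out, and wild-type ones 5, 6 and 6.

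Novelty against untreated in wild type asked which genes answer 1 h of exploration. Of 34 immediate early genes, the transcription factors and signalling genes that neurons switch on within minutes of activity, 15 rose and 19 did not pass. Egr2 (chromosome 10, 67535475 to 67542188) rose by 2.60 ± 0.36 (adjusted p = 0.00973), Fosb (chromosome 7, 19302696 to 19310051) by 2.05 ± 0.25 (adjusted p = 0.00487), and Homer1, a scaffold of the postsynaptic density, by 1.2 ± 0.21. Nptx2, a secreted pentraxin that clusters glutamate receptors, rose by 0.77 ± 0.09, and Hspa5, the main chaperone of the endoplasmic reticulum, by 0.83 ± 0.15. Kdm5c rose by 0.34 ± 0.06 (adjusted p = 0.0388), and this call ended without untreated library 1 (adjusted p = 0.195), 2 (0.164) or 3 (0.127), without novelty library 3 (0.213) and with the replicate number as a block (0.0650).

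In all, 57 genes rose and 6 fell in wild type. The immediate early genes numbered 31 past the threshold when adjusted over the list alone, with a median of 0.92 and 34 of 34 positive (camera adjusted p = 2.72e-45; adjusted p = 0.0594 with an estimated correlation). The 15 included Egr1 (1.14 ± 0.20), Klf4 (1.10 ± 0.21), Nr4a1 (1.03 ± 0.20), Gadd45b (0.96 ± 0.13), Fosl2 (0.95 ± 0.09) and Nr4a3 (0.94 ± 0.12). Fos and Arc, 2 of the most used markers of activity and named here after their values were seen, had 1.75 ± 0.35 (adjusted p = 0.0536) and 1.36 ± 0.31 (adjusted p = 0.0887). Of 20 delayed activity-regulated genes Nptx2 rose, and 11 did when adjusted over the list alone (camera adjusted p = 6.85e-12; adjusted p = 0.0838 with an estimated correlation). Of 18 glucocorticoid response genes 4 rose, and 11 when adjusted over the list alone (camera adjusted p = 3.13e-13; adjusted p = 0.0557 with an estimated correlation). These were Tsc22d3 (0.72 ± 0.11), the cell cycle inhibitor Cdkn1a (0.71 ± 0.11), the kinase Sgk1 (0.66 ± 0.08) and Errfi1 (0.60 ± 0.07). Of 19 hypoxia and heat shock genes 4 rose, and 9 when adjusted over the list alone (camera adjusted p = 7.90e-08; adjusted p = 0.0887 with an estimated correlation). These were the chaperones and folding enzymes Dnajb1 (0.85 ± 0.13), Hspa5, Pdia4 (0.81 ± 0.16) and Hsph1 (0.40 ± 0.08), none of them a hypoxia gene.

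Outside the lists Gm15344 (1.54 ± 0.21), Alkal2, a ligand of the receptor Alk (1.09 ± 0.19), Tnfrsf25 (1.02 ± 0.20) and Map3k19 (1.00 ± 0.16) rose, and 0610040B10Rik (-1.14 ± 0.21), Tipin (-0.62 ± 0.09), Nemp2 (-0.61 ± 0.11), Abhd14b (-0.53 ± 0.10), Rsrp1 (-0.43 ± 0.07) and Ccdc177 (-0.42 ± 0.08) fell. Oligodendrocyte lineage markers had a median of -0.16, none positive (camera adjusted p = 1.19e-05; adjusted p = 0.129 with an estimated correlation), and endothelial and mural markers -0.28 (camera adjusted p = 3.25e-05; adjusted p = 0.146 with an estimated correlation). H3K4 regulators had a median of 0.10 (camera adjusted p = 0.0106; adjusted p = 0.0887 with an estimated correlation) and germline genes -0.18 (camera adjusted p = 0.00879; adjusted p = 0.0887 with an estimated correlation). The count of changed genes rested on single libraries. It was 4 without novelty library 3, 5, 15 and 9 without untreated libraries 1, 2 and 3, and 102 without novelty library 1. With DESeq2 it was 214 (172 higher, 42 lower). With the replicate number as a block it was 33, and with the 6 wild-type libraries alone 6. It was 7 against a fold change of 1.2 and 252 (174 higher, 78 lower) without a low-count filter. With offsets for GC content and length it was 322 (232 and 90), and without novelty library 1 and KO novelty library 2 it was 451 (351 and 100). Fosb, Fosl2, Nptx2 and Errfi1 stayed past the threshold without any single library, 4 of the 29 named genes. Untreated libraries 1, 2 and 3 ended 24, 18 and 21 of those calls when left out, and novelty libraries 4, 9 and 25.

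In KO, novelty against untreated asked the same of mice without Kdm5c. Here 18 genes rose and none fell, and 1100 genes had an unadjusted p under 0.05. Maff, a small Maf transcription factor (chromosome 15, 79346621 to 79359076), rose by 1.82 ± 0.31 (adjusted p = 0.0492), Fosb by 1.5 ± 0.23 (adjusted p = 0.0329), Fosl2 by 0.87 ± 0.09 (adjusted p = 0.00184) and Gadd45b by 0.93 ± 0.13. Hspa5 rose by 1.00 ± 0.15 and Adcyap1, the precursor of the neuropeptide PACAP (chromosome 17, 93199017 to 93206537), by 0.87 ± 0.14. Map3k19 (1.21 ± 0.15), Plekhf1 (0.99 ± 0.16) and Arl4d (0.89 ± 0.15) rose as well.

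Of 34 immediate early genes 6 rose in KO, the others of them being Nr4a2 (0.73 ± 0.12), Arl4d and Maff, and 22 when adjusted over the list alone, with a median of 0.58 (camera adjusted p = 1.40e-34; adjusted p = 0.0780 with an estimated correlation). Of 18 glucocorticoid response genes 5 rose, and 13 when adjusted over the list alone, with 18 of 18 positive and a median of 0.49 (camera adjusted p = 2.67e-24; adjusted p = 0.00775 with an estimated correlation). These included Cdkn1a (0.82 ± 0.10), Tsc22d3 (0.82 ± 0.11), Sgk1 (0.54 ± 0.08) and Errfi1 (0.51 ± 0.07). Nptx2 (0.51 ± 0.09) rose among the delayed genes, 6 of 20 when adjusted over the list alone (camera adjusted p = 3.05e-10; adjusted p = 0.0918 with an estimated correlation). Hspa5 rose among the hypoxia and heat shock genes, 10 of 19 when adjusted over the list alone (camera adjusted p = 3.69e-13; adjusted p = 0.0694 with an estimated correlation). Mitochondrially encoded genes had a median of -0.26, none positive (camera adjusted p = 3.14e-06; adjusted p = 0.0918 with an estimated correlation). Choroid plexus markers had -0.96 (camera adjusted p = 6.06e-05; adjusted p = 0.544 with an estimated correlation), with untreated KO library 2 the high one as before. Inhibitory neuron markers had 0.14 (camera adjusted p = 0.00104; adjusted p = 0.423 with an estimated correlation), which rests on novelty library 2 at 5.92 mean log2 CPM, while novelty libraries 1 and 3 were at 5.49 and 5.58 and the untreated mean was 5.52. Camera also called microglia markers (median -0.09, adjusted p = 0.000458; adjusted p = 0.392 with an estimated correlation), blood cell genes (0.28, adjusted p = 0.00609; adjusted p = 0.225 with an estimated correlation), dentate markers (-0.14, adjusted p = 0.0235; adjusted p = 0.544 with an estimated correlation) and endothelial and mural markers (-0.08, adjusted p = 0.0370; adjusted p = 0.544 with an estimated correlation). The microglia level was 4.42 mean log2 CPM in novelty library 2 and 4.69 and 4.61 in novelty libraries 1 and 3. In the untreated KO libraries it was 4.64 to 4.75. The count of changed genes was 1 without untreated library 2 or 3 or without novelty library 1, 2 without untreated library 1, and 9 and 10 without novelty libraries 2 and 3. DESeq2 called 68 (59 higher, 9 lower) and the fit without a low-count filter 101 (77 and 24). The fit with the replicate number as a block called 6, the fit of the 6 KO libraries alone 10 and the test against a fold change of 1.2 called 1. Offsets for GC content and length gave 60 (53 higher, 7 lower), and leaving out novelty library 2 and wild-type novelty library 1 gave 63 (55 and 8). Fosl2 was the only 1 of 15 named genes that stayed past the threshold without any single library. Untreated libraries 1, 2 and 3 ended 13, 14 and 14 of those calls when left out, and novelty libraries 14, 8 and 8.

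**Figure D2:**
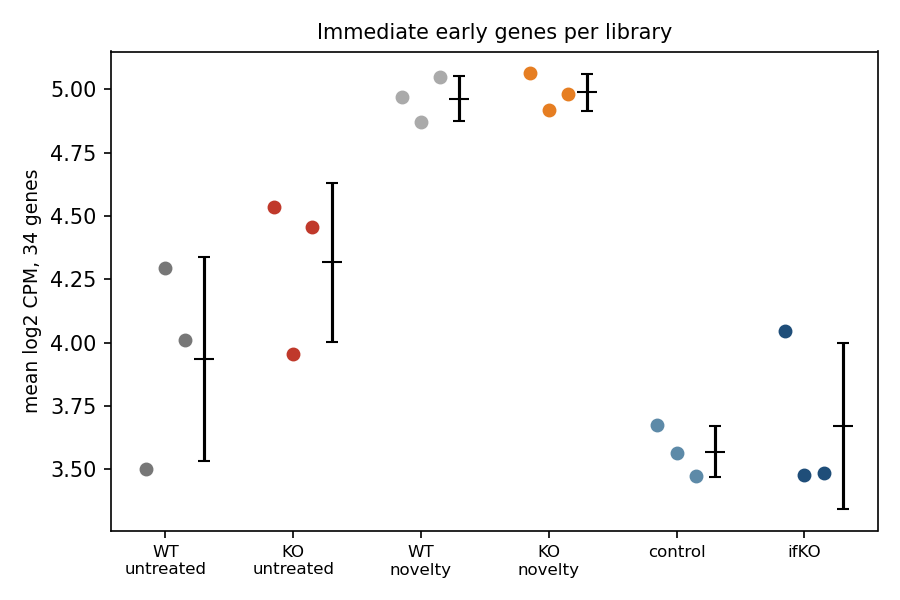
Mean log2 CPM of the 34 immediate early genes for each library (points) in the 6 groups, with the mean and SD of 3 libraries (bars). The novelty libraries of both genotypes lie between 4.87 and 5.06, above the untreated libraries of either genotype, which lie between 3.50 and 4.54.

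Whether the response to novelty differed between KO and wild type was tested as an interaction. No gene passed with edgeR and none with DESeq2, while 563 genes had an unadjusted p under 0.05, of 16392 tested, against 820 that chance alone gives. All 63 genes called in wild type had the same sign in KO. The 57 of them that rose in wild type had a median of 0.65 there and 0.43 in KO on the log2 scale. Of the 18 genes called in KO 17 had the same sign in wild type, with a median of 0.85 in KO and 0.69 in wild type, so either set was larger where it had been selected. Fosb and Egr2 were called in wild type, and Fosb also in KO, but the call of Egr2 in wild type alone does not show a difference. Immediate early genes had a median interaction of -0.31 (camera adjusted p = 1.05e-07; adjusted p = 0.408 with an estimated correlation). Their mean level after novelty was 4.96 ± 0.09 log2 CPM (SD, n = 3) in wild type and 4.99 ± 0.07 in KO, and before it 3.94 ± 0.40 and 4.32 ± 0.32. Mitochondrially encoded genes had -0.29 (camera adjusted p = 6.72e-06; adjusted p = 0.224 with an estimated correlation), and oligodendrocyte lineage markers 0.18 (camera adjusted p = 6.97e-05; adjusted p = 0.312 with an estimated correlation). Camera also called inhibitory neuron markers (median 0.16, adjusted p = 0.000992), choroid plexus markers (-0.98, adjusted p = 0.00174), dentate markers (-0.21, adjusted p = 0.00379), thalamus, striatum and habenula markers (0.31, adjusted p = 0.00388), synaptic genes (-0.08, adjusted p = 0.0220), germline genes (0.10, adjusted p = 0.0260) and endothelial and mural markers (0.13, adjusted p = 0.0285). For these 7 lists the adjusted p with an estimated correlation lay between 0.224 and 0.533. Without a low-count filter 8 genes passed. Kdm5c had -0.25 ± 0.09 (unadjusted p = 0.0153). In simulated counts of this design, which lack any trend with GC content and length, 35.8% of 1.5-fold and 81.6% of 2-fold interactions were recovered. With wild-type novelty library 1 and KO novelty library 2 both left out 331 genes passed, 29 higher and 302 lower, and 16 when an offset for GC content and length was added. Of the 9 ways to leave out 1 novelty library of either genotype this is the 1 that sets genotype along that trend, and the other 8 gave at most 1 gene.

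The comparison of ifKO with its control asked what follows when Kdm5c is deleted in adult forebrain neurons. Cacng6 rose by 3.42 ± 0.13, from 1.19 to 12.7 CPM (adjusted p = 6.21e-08), and Klk10 by 2.48 ± 0.21, as both had in KO. Dnah1, an axonemal dynein heavy chain (chromosome 14, 31260375 to 31323896), rose by 1.99 ± 0.06 (adjusted p = 2.39e-08). Esr1, oestrogen receptor alpha (chromosome 10, 4611593 to 5005614), rose by 2.89 ± 0.11, from 3.66 to 27.3 CPM, in a line whose Cre is fused to part of the human oestrogen receptor. Arsi, an arylsulfatase gene (chromosome 18, 60911780 to 60918561), rose by 2.71 ± 0.14 and lies beside Camk2a, whose promoter drives that Cre. Ogn fell by -1.29 ± 0.15 (adjusted p = 0.00100).

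In all, 107 genes rose and 5 fell of 17367 tested. The noncoding RNAs 3300002P13Rik (2.91 ± 0.25), next to Cacng6, and 6430584L05Rik (1.95 ± 0.11) rose, as did Amn (1.74 ± 0.32), Ido2, an enzyme of tryptophan breakdown (1.60 ± 0.12), and Jsrp1 (1.55 ± 0.14). Mcm6 (-0.34 ± 0.06), Zfhx2 (-0.32 ± 0.04), the metalloprotease Bmp1 (-0.28 ± 0.05) and the neuropeptide Y receptor Npy2r (-0.22 ± 0.04) fell. None of 16 measured germline genes passed, over all genes or adjusted over the list alone (median -0.08, camera adjusted p = 0.419). Of the 7 that rose in KO only Ddx4 (-0.19 ± 0.11), Sycp3 (-0.09 ± 0.33) and Tex14 (-0.25 ± 0.26) were tested in ifKO. Naa11, Stk31, Cyct and D1Pas1 had too few counts to be tested, with 18, 17, 6 and 2 over the controls and 4, 6, 2 and 2 over ifKO. Summed over the 7 genes that rose in KO, the level was 6.01 ± 0.855 counts per M (SD, n = 3) in ifKO and 7.10 ± 0.116 in the controls.

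No list had a member past the threshold over all genes in ifKO. Mitochondrially encoded genes had a median of -0.11 (camera adjusted p = 5.69e-05; adjusted p = 0.668 with an estimated correlation), dentate markers -0.06, with 1 higher and 4 lower when adjusted over the list alone (camera adjusted p = 0.0221; adjusted p = 0.668 with an estimated correlation). Interferon and antigen presentation genes had a median of 0.22, with 20 of 20 positive (camera adjusted p = 2.19e-05; adjusted p = 0.668 with an estimated correlation). Microglia markers had 0.10, with 15 of 15 positive (camera adjusted p = 0.000368; adjusted p = 0.668 with an estimated correlation). Choroid plexus markers had -1.21 (camera adjusted p = 1.28e-05; adjusted p = 0.668 with an estimated correlation), and their level was 2.75 mean log2 CPM in control library 1 against 0.20 to 0.96 in the other libraries of the line. Immediate early genes had 0.14 (camera adjusted p = 0.00441; adjusted p = 0.782 with an estimated correlation), which rests on ifKO library 1 at 4.05 mean log2 CPM, while ifKO libraries 2 and 3, both at 3.48, lay below the control mean of 3.57. Synaptic and glutamatergic genes had 0.03, with 19 of 24 positive (camera adjusted p = 0.00265; adjusted p = 0.668 with an estimated correlation), and astrocyte markers 0.04, with 13 of 14 positive (camera adjusted p = 0.0212; adjusted p = 0.668 with an estimated correlation). Single libraries also stood apart for the dentate list (ifKO 1 at 5.84, others 5.97 to 6.00), the mitochondrial list (control 1 at 7.05, others 6.83 to 6.95), and the microglia and interferon lists (control 3 at 4.57 and 2.65, others from 4.71 and 2.80 up). Noncoding genes made up 21.5% of the higher genes against 14.8% (Fisher's exact test, two-sided, p = 0.0566), and none of 80 genes within 10 Mb of Kdm5c was called (Fisher's exact test, two-sided, p = 1). The count was 56, 71 and 72 without control library 3, control library 2 and ifKO library 2, 49 against a fold change of 1.2 and 398 (322 higher, 76 lower) without a low-count filter. Of the 10 named higher genes 9, and of the lower genes Ogn and Zfhx2, stayed past the threshold without any single library. Control libraries 1, 2 and 3 ended 3, 4 and 3 of the 15 calls when left out, and ifKO libraries 3, 2 and 2.

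The constitutive and the inducible mutant shared much of their change. Among 16159 genes tested in both, 76 rose in both and 3 fell in both, where n1 × n2 / N gives 1.08 and 0.008, and none changed in opposite directions. The shared genes included Cacng6, Klk10, Arsi and Ogn. Of 111 genes called in ifKO 110 had the same sign in untreated KO (r = 0.761 across genes), and of 191 called in untreated KO 165 had the same sign in ifKO (r = 0.452 across genes). Over the genes of the latter set that rose in KO, also 165 in number, the median ratio of the ifKO to the KO change was 0.59. Over the 106 called genes that rose in ifKO, the median ratio of the KO to the ifKO change was 1.12 (medians 0.79 in KO and 0.73 in ifKO). These comparisons share no library.

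**Figure D3:**
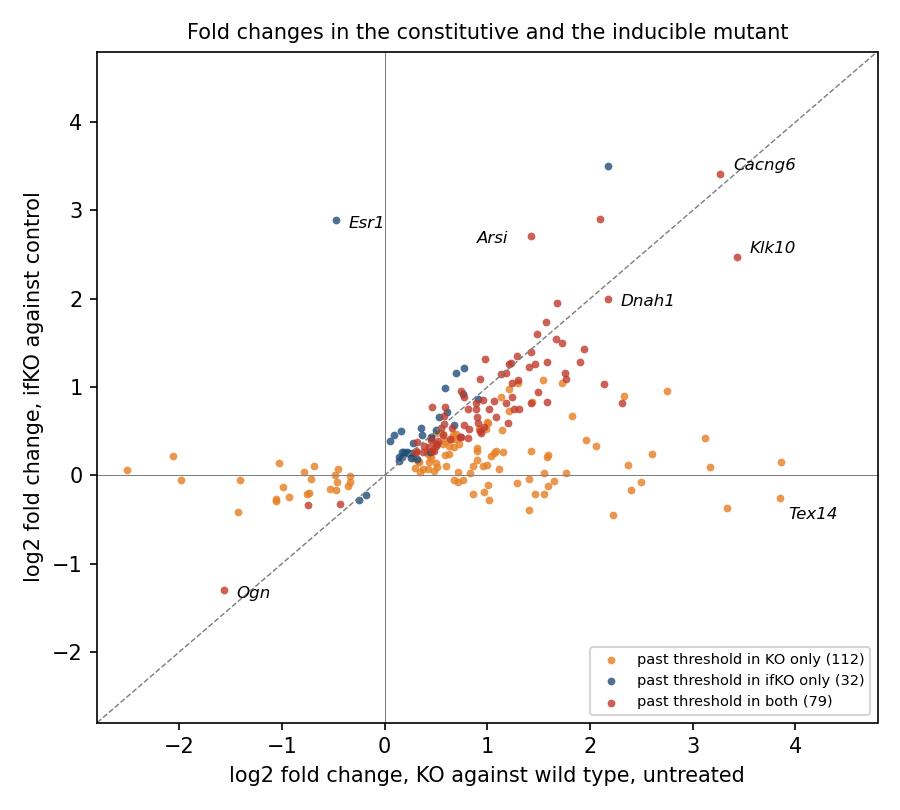
Log2 fold change in ifKO against that in untreated KO for each gene past the threshold in either, coloured by where it passed, with the line of equal change dashed. The 79 genes past it in both changed in the same direction in both, while Tex14 was near 0 in ifKO and Esr1 rose in ifKO alone.

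Whether a gene's change differed between KO and ifKO was tested in a fit of all 18 libraries, with each mutant set against its own control. Of 17508 genes 19 had a higher effect in KO and 1 a lower one, the latter being Esr1 (-3.38 ± 0.21, adjusted p = 1.04e-07). Tex14 had 4.11 ± 0.29 (adjusted p = 3.10e-07), Gm28286 3.99 ± 0.51, A830008E24Rik 3.70 ± 0.44 and Stk31 4.74 ± 0.84. Naa11 had a fitted value of 7.38 ± 1.25 that rests on few counts, 18 in the controls and 4 in ifKO. Of 24 germline genes 3 differed, and 7 when adjusted over the list alone, with a median difference of 0.47 (camera adjusted p = 2.02e-09; adjusted p = 0.00192 with an estimated correlation). Choroid plexus markers had 2.56, with 12 past the threshold when adjusted over the list alone (camera adjusted p = 2.41e-09; adjusted p = 0.321 with an estimated correlation), from KO untreated library 2 and control library 1. Interferon and antigen presentation genes had -0.31, none of 20 positive (camera adjusted p = 2.12e-07; adjusted p = 0.321 with an estimated correlation), and immediate early genes 0.22 (camera adjusted p = 0.000634; adjusted p = 0.586 with an estimated correlation). Mitochondrially encoded genes had 0.19, with 11 of 11 positive (camera adjusted p = 0.000634; adjusted p = 0.321 with an estimated correlation), and oligodendrocyte lineage markers -0.16 (camera adjusted p = 0.000641; adjusted p = 0.321 with an estimated correlation). Blood cell genes had -0.22 (camera adjusted p = 0.0115; adjusted p = 0.321 with an estimated correlation) and astrocyte markers 0.10 (camera adjusted p = 0.0400; adjusted p = 0.324 with an estimated correlation). Tex14, Gm28286, A830008E24Rik and Esr1 stayed past the threshold without any single library. DESeq2 called 44 genes (36 higher, 8 lower) and the fit without a low-count filter 83 (65 and 18). Naa11 lost its call without wild-type untreated library 2 (7.32) and without control library 2 (6.92) or 3 (7.32). Stk31 lost its call without control library 1 (4.40) or 2 (4.66), without ifKO library 1 (5.06), 2 (4.76) or 3 (4.49), and without wild-type untreated library 1 (4.72) or 2 (4.31). Line, background, read layout and flowcell differ between the mutants together and cannot be separated.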

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

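The values that stood out all come from the test of whether an effect differs between KO and ifKO, and stood out because they passed it. They are Naa11 at 7.38, Stk31 at 4.74, Tex14 at 4.11, Gm28286 at 3.99, A830008E24Rik at 3.70 and Esr1 at -3.38 on the log2 scale, the 20 genes that differed in all, and the germline genes with a median difference of 0.47. The tests of the 3 patterns below (Esr1, germline genes, novelty libraries) were chosen after the results were seen, while the counts of other splits of the libraries were planned. The bounds by which 2 of them are read were also changed after a first value had been computed. By the first bounds the depth test left depth open and the marker test excluded another cell type, and by the later bounds each reads the other way, so neither reading carries weight by itself.

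Esr1 rose in ifKO and not in KO (difference -3.38). Reads of the creERT2 transgene, which carries part of the human ESR1 sequence, may be counted as Esr1, and the difference between a line with and a line without the transgene fits this. A rise of Esr1 through loss of Kdm5c is excluded in untreated KO, at -0.48 ± 0.17, while a rise through its loss in adult neurons alone stays open. Copies of the Camk2a promoter region with the transgene cannot explain the rise of Arsi in untreated KO (1.42 ± 0.25), a line without the transgene. By the bound of this test they were excluded as the whole cause of a rise of Arsi. The test does not read ifKO, however, so such copies may still account for the rise of 2.71 ± 0.14 there. For Slc6a7, also beside Camk2a, the difference of -0.34 (SE 0.12, adjusted p = 0.997 with edgeR) leaves such copies open, and whether the controls carry the transgene is not given in the sources used here.

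Of the 7 germline genes that rose in KO, Ddx4, Sycp3 and Tex14 were tested in ifKO and did not pass, and the other 4 had too few counts there to be tested. Lower depth is excluded by the later bound: the ifKO libraries hold at most 268 counts of the 7 genes, at 36.3 to 43.1 M counts, against 614 in untreated KO library 2 at 22 M. The other genes higher in KO after novelty that were tested in ifKO had a median ratio of ifKO to untreated KO of 0.605 (180 genes). Resampling these genes gave a 95% interval of 0.574 to 0.671, which takes genes as independent and leaves out error between pools. The set was chosen by the novelty contrast, whose filter and fitted spread also used the untreated libraries. These values argue against dilution of every effect alike, by deletion in a part of the cells. As 0 of the 7 lie within 20 Mb of Kdm5c, which their known positions fixed beforehand, 129 sequence there is excluded only as a cause in cis. When and in which cells Kdm5c was lost, the background elsewhere in the genome, the read layout and the flowcell were not tested and stay open.

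The novelty libraries part into sets that cut across genotype: wild-type 1 with KO 1 and 3 against wild-type 2 and 3 with KO 2 gives 1284 genes, several times the 219 of the real split, which points to a structure of the samples. A trend with GC content and transcript length may be its source, at least in part. Offsets for both bring the 1284 to 0, and the 331 interaction genes found without wild-type 1 and KO 2 to 16. Between the sets 2001 genes still had an unadjusted p under 0.05, against 4541 before the offsets and 820 by chance. Some difference thus remained. The offsets were fitted to these same libraries and take out whatever follows GC content or length, so the fall does not show the source. Swapped labels are excluded, since KO 2 lies 1.12 above wild-type 1 for the genes higher in KO, against a gap of 1.24 between the untreated genotypes. RNA of another region stays open by the later bound, with 41.7% of the dentate markers called (5 of 12, median -0.38, and -0.09 with offsets). What gave the trend cannot be read from the counts.

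For 5 comparisons of 3 against 3 libraries the 10 splits are too few for a share under 0.05. The real and the highest other counts are 204 and 0 for untreated KO (1 split as large, the real one), 219 and 1284 for KO after novelty (2 splits), 63 and 0 for novelty in wild type (1), 18 and 0 for novelty in KO (1), and 112 and 0 for ifKO (1). For the interaction, 46 of 80 splits gave as many genes at an unadjusted p under 0.05 as the real 563, up to 4094, so chance is not excluded. For the difference between KO and ifKO, 4 of 60 splits gave 20 genes or more, up to 77. By the share of 0.05 set beforehand chance is not excluded here either. The 3 others keep the real KO and wild-type groups and mix only ifKO with control, so they carry the effect of KO. That reading was not part of the plan and does not change its outcome. The drawn splits that mix KO with wild type gave at most 2 genes. Such mixing puts the effect of KO into the fitted spread, so few calls there do not exclude chance.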

How the results depend on the processing

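With DESeq2 the counts that moved were 214 for novelty in wild type, 68 for novelty in KO and 44 for KO against ifKO. Without a low-count filter they were 347 for untreated KO, 252 and 101 for novelty in wild type and KO, 8 for the interaction, 398 for ifKO and 83 for KO against ifKO. Against a fold change of 1.2 they were 122, 126, 7, 1 and 49 for untreated KO, KO after novelty, novelty in wild type, novelty in KO and ifKO, as a stricter question must lower them. With only the groups compared they were 318, 104, 6 and 10 for the first 4 of these. With the replicate number as a block they were 33 and 6 for novelty in wild type and KO. Between groups, same-number libraries had a median r of -0.012 and other pairs -0.0175, with 2 of 18 same-number pairs above 0.1. The highest of these 18, 0.302, was between novelty libraries 2 of wild type and KO. In the inducible line the medians were -0.078 and 0.014, with 0 of 3 same-number pairs above 0.1. The medians gave no sign of pairing by number, but cannot show whether libraries of 1 number were prepared together. Leaving out 1 library gave 121 to 149 for untreated KO, 144 to 282 for KO after novelty, 4 to 102 and 1 to 10 for novelty in wild type and KO, and 56 to 102 for ifKO. At an adjusted p under 0.01 the shared genes were 46 for KO with ifKO and 93 for both treatments. Of the 147 list tests 60 passed with the preset correlation, 4 with an estimated correlation and 14 with fry, each counted by itself. Chosen after seeing the data, leaving out both deviating novelty libraries gave 415, 705, 451, 63 and 331 for untreated KO, KO after novelty, novelty in wild type, novelty in KO and the interaction. For KO after novelty (406 higher, 299 lower) and the interaction this sets genotype along the GC and length trend, and the other 8 such pairs gave at most 1 interaction gene. Also chosen then, offsets for GC content and length gave 340, 354, 322 and 60 for the first 4 and 0 for the interaction. Apart from the fold threshold the cause was not tested. Over the named genes alone, 1007 alternatives left the result the same, 329 were weaker, 2 stronger and none reversed. The lists are not part of these counts.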

Other observations

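No other member of the Kdm5 family passed the threshold in either mutant. Kdm5a had a log2 fold change of 0.15 in untreated KO and -0.01 in ifKO, Kdm5b -0.01 and 0.05, and the Y-linked Kdm5d 0.10 and -0.05 with edgeR. These genes, like Dnah1 and Parvg here, were named after their values were seen. Between the mutants, some genes rose alike: Dnah1 rose by 2.17 in untreated KO and 1.99 in ifKO, and Parvg, gamma-parvin, by 1.28 and 1.35.

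The tests of neighbouring genes in this part were written before their outcome was known, after some pairs had been noticed. Genes higher in untreated KO may rise together with their neighbours: 14 pairs of the 178 higher genes lie within 100 kb of each other, against a median of 3 and at most 17 in 10000 random sets of like expression (permutation p = 4e-04). Among them are Cacng6 with 3300002P13Rik, Parvb with Parvg, and Fbxw23 with Gm42756 and Gm43089. A set of 3 neighbours counts as 3 pairs, so the 14 are not independent. Reads shared between overlapping or same-strand neighbours within 1 kb could explain 3 of the 14 pairs, too few by the bound set beforehand. That count rests on the 1 kb limit and on strand, while the strand setting of HTSeq is not given. Cacng6 and 3300002P13Rik lie 750 bp apart on opposite strands, and Pdzd3 and Nlrx1 1246 bp apart on the same strand. Shared reads are therefore not excluded by this second test. This second test was for a time taken out once its value was known, and was then put back as first written. Transcription that runs on from 1 gene into the next was not tested. The neighbours are thus a hypothesis from the data they were found in.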
